A study of Mus musculus with 2 samples.

How the data were processed

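Colon mucosal scrapings came from C57BL/6 mice given 3% DSS for 3 days. Per the labels' protocols the mice were 6 to 8 weeks old, while the design text gives 7 weeks; total RNA was extracted with Trizol, and biotin-labelled amplified RNA was prepared from 250 ng. The series has 2 samples, 1 per genotype, assigned to Hif-2αF/F or Hif-2αΔIE from the genotype label. The labels do not spell out ΔIE; it is read here, from knowledge of this mouse model, as deletion in the intestinal epithelium. The design text counts 6 and 5 mice per genotype; whether each array holds pooled RNA or 1 animal is not given in the sources used here.

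The deposited file is a value table of 45101 probe sets by 2 samples. Its values are log2 expression, which the authors made with the affy package and RMA (background correction, quantile normalization and summary of each probe set), per the submitters' processing notes; versions, the arrays normalized together and any filter are not given in the sources used here. The values ran from 2.27 to 14.43 for F/F and from 2.31 to 14.48 for ΔIE, with medians of 6.12 and 6.11, and the sorted columns lay at most 0.16 apart. For 1699 probe sets both columns held the same value to every printed digit. RMA gives no detection call and compresses differences of dim probe sets, and quantile normalization sets the distributions of the arrays equal, so that a change in total RNA or in the majority of genes would not be seen. Each value rests on 1 array, so the number of arrays limits the precision; no counting error applies.

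Gene names came from a platform annotation table paired with the file. It gave 1 symbol for 34958 probe sets, several for 932 and none for 9211, and probe sets with several or none were left unnamed; 0 symbols changed when looked up by Entrez ID in a gene table of assembly GRCm38.p6, and 204 probe sets whose ID was not in it kept theirs. No genome build belongs to the file, so no coordinates are given. The 64 control probe sets, 13 of which carried a gene symbol, were kept out of the gene comparison, a choice made after values had been seen. A gene took the value of its probe set with the highest mean of both arrays, which gave 18193 genes. A gene was kept where its higher value reached the median of all probe sets' means, 6.11, which left 11899 genes. Older symbols in the lists were matched through synonyms.

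Because each group holds 1 array, no test between genotypes was run. Differences are ΔIE minus F/F on the log2 scale, a fold is 2 raised to their size, and genes were counted at 2-fold. The text names, by a rule fixed before the data were examined, Epas1, Hif1a, Arnt and Vhl, genes among the 15 with the largest difference in each direction, in each list up to 6 members of largest difference or all at 2-fold, and control probe sets. Members of a list with a small difference that are named beside them, Cybrd1, and Hox genes outside the fixed list were chosen after their values were seen. For each of the 35 lists, which cover pathways, cell types of the mucosa, tissues a scraping could carry, position along the gut, handling stress, clock and Y-linked genes, the median over the genes kept was set against 10000 random lists of the same size drawn within 20 bins of equal size by mean expression. A list was said to stand apart below the 2.5th or above the 97.5th percentile. Genes within a list vary together, so this range describes the arrays and is narrower than the variation between mice would be.

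Data were simulated for 11899 genes with independent noise scaled to the middle of the observed differences. There, 100.0% of 66 genes changed 4-fold, 50.7% of 67 changed 2-fold and 8.96% of 67 changed 1.5-fold were counted at 2-fold. Of unchanged genes, 0.487% were counted too. Of the 35 lists, 2 lay outside the range when nothing was changed and 32 lay below it when lowered by 0.3. The noise left out the wide tails of the observed differences (SD 0.49, quartiles -0.18 and 0.19). It also left out the shared variation of genes within a list. These rates therefore describe the simulation and are not error rates of the real arrays. Alternatives tried were the mean over a gene's probe sets, leaving out probe sets whose ID ends in _s_at or _x_at, no filter, a filter at the 75th percentile or on both arrays, median centring, a lowess correction (span 0.3), thresholds of 1.5-fold and 3-fold, agreement of all probe sets, list means and unmatched random lists; leaving out list members shared with another list was added after seeing the data. A gene was taken to have moved where an alternative shifted it by over 0.41, and a list where its median shifted by over 0.5 times the width of its random range; both limits were set after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.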

Results

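Gene expression was measured in colon mucosal scrapings of C57BL/6 mice that had been given 3% dextran sulfate sodium (DSS), a polysaccharide that injures the colonic mucosa, for 3 days. The comparison was between Hif-2αF/F mice, which carry conditional alleles of Epas1, the gene of the hypoxia-inducible transcription factor HIF-2α, and Hif-2αΔIE mice, in which the gene is removed from the intestinal epithelium. It addresses which colonic transcripts depend on epithelial HIF-2α while DSS injury sets in. The design text counts 6 F/F and 5 ΔIE mice, but the data hold 1 array per genotype, and whether RNA of the mice was pooled is not given in the sources used here. No test, standard error or p-value between genotypes could therefore be given, and every difference below compares these 2 arrays. The values are log2 expression after robust multi-array averaging (RMA), and differences are ΔIE minus F/F. Of 45101 probe sets, 34958 carried a single gene symbol. After control probe sets were set aside, 11899 genes reached the expression filter, and the values of these genes correlated at Pearson r = 0.96 between the arrays, a correlation across genes.

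The genotype labels were checked first. The array carries 4 control probe sets for bacteriophage Cre recombinase, and these read between 2.92 and 4.22 on the F/F array and between 7.86 and 10.01 on the ΔIE array. The 41 other bacterial control probe sets, including those for the bioB, bioC and bioD transcripts, differed by -0.17 to 0.43 on the log2 scale, with medians of 3.11 on the F/F array and 3.14 on the ΔIE array. Cre sequence was thus detected on the array labelled ΔIE and not above the level of the other bacterial controls on the array labelled F/F. Epas1 itself hardly differed: its brighter probe set read 11.90 in F/F and 11.77 in ΔIE, a log2 difference of -0.13, and its dimmer one read 6.98 and 7.15. The position of these probe sets relative to the deleted part of the gene was not determined here, and a probe set outside that part would not register the deletion. Hif1a, the gene of the related subunit HIF-1α, was lower on the ΔIE array by 0.97 on the log2 scale (12.38 against 11.41), and its 2 dimmer probe sets above the filter differed by -1.15 and -1.17. Lists of neutrophil (-1.57), macrophage (-1.07) and matrix (-0.92) genes, described below, were lower on the same arrays. Whether the Hif1a difference came from the deletion was not tested. Arnt, the gene of the shared partner subunit, differed by -0.03, and Vhl, the gene of the ubiquitin ligase subunit that targets HIF-α for degradation, by -0.15.

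More genes were lower than higher on the ΔIE array. At a difference of at least 2-fold, 631 genes (5.30% of those kept) were lower and 137 (1.15%) were higher, while the median over all genes kept was 0.02 and the quartiles were -0.18 and 0.19. The lowest was Mptx1, which encodes a mucosal pentraxin of the gut epithelium, at 9.31 in F/F and 3.87 in ΔIE. Where a value lies below the expression filter, 6.11, on 1 array, both values are given in place of a fold. The epithelial crosslinking enzyme gene Tgm3 read 11.15 in F/F and 7.34 in ΔIE, and with probe sets averaged it differed by -3.35 in place of -3.81. The beta-defensin gene Defb3 was 10.5-fold lower, and the matrix metalloproteinase genes Mmp10 and Mmp3 8.38-fold and 6.21-fold. Slc15a1 (the intestinal peptide transporter PEPT1) read 7.19 in F/F and 4.37 in ΔIE, and Khdc1a 7.84 and 5.10. By their brightest probe sets, Ctse (cathepsin E), Sval1 and Thbs4 (a thrombospondin) were 7.42-fold, 7.01-fold and 6.17-fold lower. Averaged over its 2 probe sets, Ctse differed by -1.39 in place of -2.89, so its dimmer probe set was not lower. The remaining genes among the 15 lowest were Hoxb13 and Hoxd13, Insl5, and the B cell genes Ms4a1 and Ighm, which are described with their groups. The highest by its brightest probe set was Iapp, the gene of the islet and enteroendocrine peptide amylin, at 6.35 in F/F and 8.45 in ΔIE, a 4.27-fold difference. Mylpf and Tnnc2, which encode contractile proteins of fast skeletal muscle, were 4.27-fold and 3.66-fold higher, the sulfate transporter gene Slc13a1 4.07-fold, the transcription factor gene Osr2 3.86-fold and the aldo-keto reductase gene Akr1c21 3.54-fold. The cytochrome P450 gene Cyp3a25 read 5.91 in F/F and 7.78 in ΔIE, and the morphogen gene Shh 5.89 and 7.63. Averaged over their probe sets, Osr2 differed by 1.21 in place of 1.95 and Iapp by 1.52 in place of 2.09, below Mylpf. For 5110 genes with more than 1 probe set above the filter, the differences of the 2 brightest probe sets lay a median of 0.10 apart, and 95% lay within 0.41. Of these genes 231 were at least 2-fold by the brightest probe set. The second probe set had the same sign for 97.8% of the 231 and was also at least 2-fold for 74.0%.

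**Figure D1:**
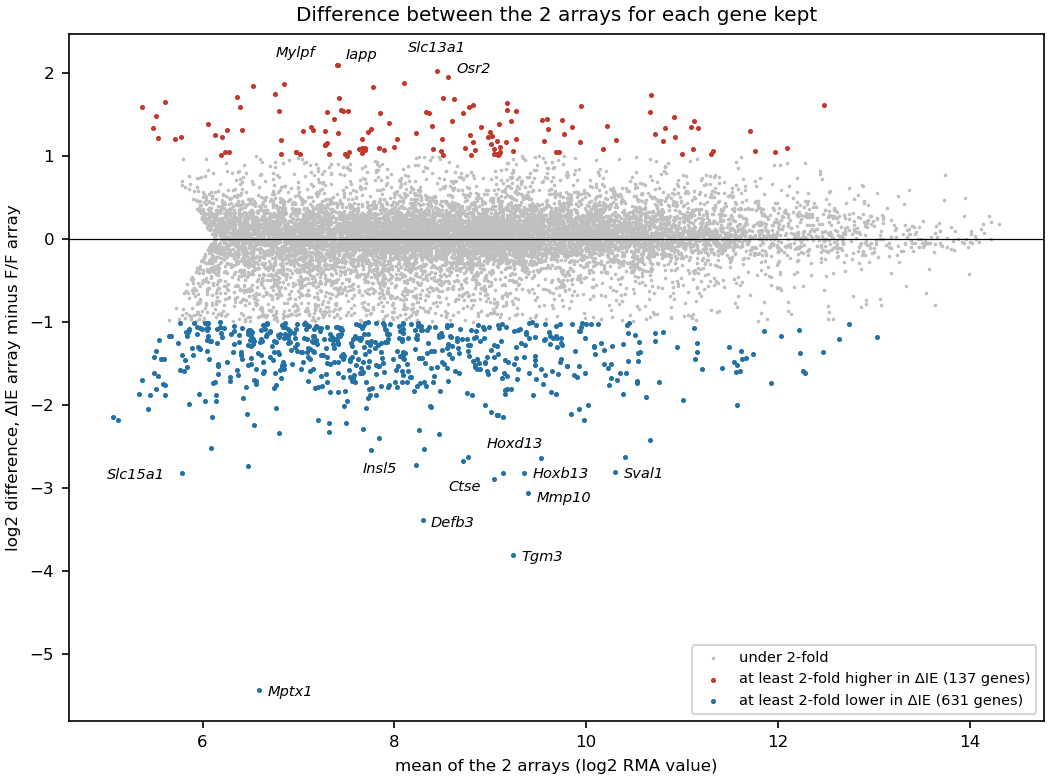
Each point is a gene kept by the filter, with the mean of the 2 arrays (log2 RMA value) on the x axis and the log2 difference, ΔIE minus F/F, on the y axis. Blue points are the 631 genes at least 2-fold lower on the ΔIE array and red points the 137 at least 2-fold higher; the named genes are among the 15 with the largest difference in each direction.

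The genes were then grouped by 35 lists chosen before the data were examined. A list's median difference was set against the middle 95% of 10000 random lists of the same size and expression, as a description of these 2 arrays. By this measure 12 lists lay below that range, 9 above it and 14 within it. If list members were independent draws, 1.75 lists would be expected outside. Genes within a list vary together and some lists share members, so the count cannot be judged against that number.

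Cytokine, chemokine and leukocyte transcripts were lower on the ΔIE array. Both arrays are of DSS-treated mice, so whether these transcripts responded to injury was not measured. All 28 cytokine and chemokine genes kept were lower, 15 of them at least 2-fold, with a median of -1.05 (random lists -0.12 to 0.13). Ccl20, which attracts dendritic cells and lymphocytes, was 4.93-fold lower and Il1b 4.32-fold, and Il6 read 7.00 in F/F and 5.05 in ΔIE. The neutrophil-attracting chemokine genes Cxcl1, Cxcl2, Cxcl3 and Cxcl5 were 3.19-fold, 2.97-fold, 2.73-fold and 2.61-fold lower, and Il17a was 2.93-fold lower. Tnf was 1.64-fold lower, at 7.13 in F/F and 6.42 in ΔIE, and Il18 differed by -0.23. All 17 neutrophil genes kept were lower as well, 15 at least 2-fold, with a median of -1.57, among them Camp (3.65-fold), Stfa2l1 (3.49-fold), Trem1 (3.45-fold) and Csf3r (2.96-fold). The abundant neutrophil calprotectin genes S100a8 and S100a9 were 1.58-fold and 1.74-fold lower, from levels near the top of the scale. All 22 macrophage and monocyte genes kept were lower with a median of -1.07, including Clec7a (3.06-fold), Ccr2 (2.70-fold), Tyrobp (2.59-fold) and Cd68 (2.28-fold), and Cd163 and Cx3cr1 differed by -0.26 and -0.29. Class II antigen presentation genes had a median of -0.88 over 10 genes, all lower, with H2-Ob 4.54-fold and H2-Aa 1.99-fold lower. The Hox genes of paralog groups 10 to 13, which mark the posterior gut, had a median of -1.49 on the same arrays, and squamous epithelium genes a median of -1.17.

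Among lymphocyte markers, all 17 B and plasma cell genes kept were lower, with a median of -1.49; the mature B cell genes Ms4a1, Cd79b and Cd22 were 6.41-fold, 3.69-fold and 3.32-fold lower and Cr2 read 7.17 in F/F and 5.02 in ΔIE, while the plasma cell transcripts Igha and Jchain were 1.34-fold and 1.73-fold lower. Ighm was 6.23-fold lower by its brightest probe set, but its probe sets above the filter ranged from -3.998 to -0.03, the average over its probe sets was -1.19, and immunoglobulin probe sets can match several gene segments. The 15 T and NK cell genes kept had a median of -0.20, within the random range of -0.24 to 0.17, but without a filter the median was -0.18, below its range, and against random lists not matched on expression -0.20 lay below the range too. The difference between B and T cell lists was not tested. Of the T and NK cell genes only Icos passed 2-fold (2.74-fold lower), and Cd3e differed by -0.20 and Gzma by 0.13. Of mast cell and eosinophil genes, 4 were kept, with a median of -0.26 inside the random range (-0.18 without a filter, below its range), and of blood and red cell genes 3 were kept, with a median of -0.45, also inside it. The posterior Hox genes (-1.49) differed on the same arrays as the B cell genes.

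The fibroblast and extracellular matrix list had a median of -0.92, with 26 of 27 genes lower and 8 at least 2-fold, among them Mmp13 (5.77-fold), Timp1 (2.54-fold) and Col1a1 (2.29-fold), and Col6a2 differed by 0.02. All 23 endothelial genes kept were lower, with a median of -0.59; Lyve1, a marker of lymphatic endothelium, was 2.10-fold lower and Pecam1 1.80-fold. Smooth muscle genes had a median of 0.10 and enteric neuron and glia genes a median of 0.02, both inside their random ranges. The mean over smooth muscle genes, 0.18, lay above its range. Of the 22 smooth muscle genes 15 were above 0 and 7 below, and only Actc1 (2.07-fold) and Ckm (2.04-fold) were 2-fold higher. With probe sets averaged, Ckm differed by 0.58 in place of 1.03. The skeletal muscle genes Mylpf and Tnnc2 were higher on the same arrays (4.27-fold and 3.66-fold), so these 2 members are not read as smooth muscle. Acta2 differed by -0.08 and Myh11 by 0.08. Adipose genes were higher, with 12 of 13 above 0 and a median of 0.71, including Retn (1.98-fold), Pck1 (1.92-fold) and Adipoq (1.74-fold).

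Genes that mark the position along the gut also differed, on the same arrays. Hox genes pattern the body axis, and the paralog groups of high number are expressed towards its posterior end. All 7 Hox genes of groups 10 to 13 that were kept were lower on the ΔIE array, with a median of -1.49. That median is the value of Hoxd11, which read 7.00 in F/F and 5.51 in ΔIE, below the filter. Hoxa10 (5.71) and Hoxa13 were also below the filter on the ΔIE array, so the size of the median is uncertain. Hoxb13 read 10.76 in F/F and 7.94 in ΔIE (7.10-fold lower), Hoxd13 10.54 and 7.72 (7.07-fold), Hoxa13 6.47 and 4.71, and Hoxd10 was 2.71-fold lower. Averaged over its probe sets, Hoxd13 differed by -2.20 in place of -2.82. The 12 Hox genes of lower groups went both ways. Hoxb5, Hoxb6 and Hoxb9 were 2.04-fold, 2.36-fold and 2.20-fold higher, whereas Hoxa9 was 3.51-fold and Hoxa5 1.85-fold lower. With probe sets averaged, Hoxa9 differed by -1.39 in place of -1.81. All 7 Hoxa genes kept were lower, and of 7 Hoxb genes only Hoxb13 was. Cdx2, a regulator of intestinal identity, was 2.03-fold higher. Because the members went both ways, the list median of -0.38 describes the group poorly, and its sign depended on the expression filter: it was 0.37 with a filter at the 75th percentile and 0.11 when both arrays had to pass the filter. Genes of keratinised squamous epithelium, a tissue that begins at the anorectal junction, were lower too, with 12 of 13 below 0 and a median of -1.17; Krt14 read 12.40 in F/F and 10.81 in ΔIE, Krt5 12.30 and 10.94, and Krt13 was 3.27-fold lower. The small intestine list had a median of 0.20 over 11 genes, just above its random range of -0.23 to 0.19, with 6 genes above 0 and 5 below. It lay within the range as a mean over members (0.08), with probe sets averaged (0.18), without members shared with another list (0.05), an alternative chosen after seeing the data, and against random lists not matched on expression.

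**Figure D2:**
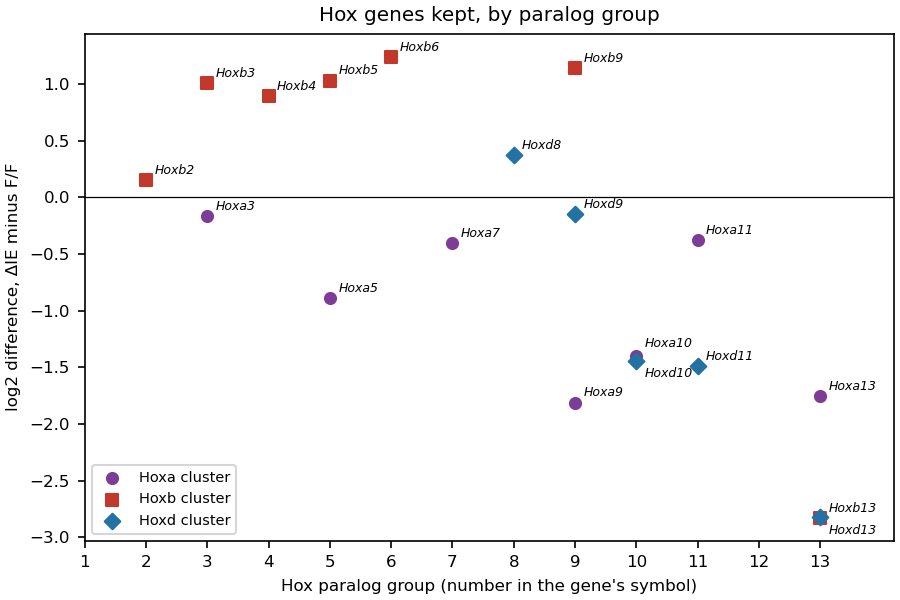
Log2 difference, ΔIE minus F/F, of the 19 Hox genes kept (y axis) by paralog group (x axis); colours and shapes give the gene cluster and each point is 1 gene on 1 array per genotype. All 7 genes of groups 10 to 13 lie below 0, the 5 Hoxb genes of groups 3 to 9 lie between 0.90 and 1.24, and all 7 Hoxa genes lie below 0.

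Hypoxia and iron genes were examined because HIF-2α is known to act on both. The HIF and hypoxia list was lower by a small amount: 26 of 37 genes were below 0, 6 of them at least 2-fold, and the median was -0.23 against a random range of -0.06 to 0.13. The prolyl hydroxylase gene Egln3 was 3.33-fold lower, the glucose transporter gene Slc2a3 2.89-fold, the collagen crosslinking gene Lox 2.87-fold, the lactate transporter gene Slc16a3 2.35-fold, Pfkfb3 2.24-fold and Ankrd37 2.10-fold. Averaged over their probe sets, Slc2a3 differed by -0.70 in place of -1.53 and Lox by -0.93 in place of -1.52. No list member was 2-fold higher; Ndrg1 differed by 0.69, Car9 by 0.27, Vegfa by 0.20, Pgk1 by -0.24 and Ldha by -0.16. Iron genes as a list did not stand apart, with 11 genes above and 11 below 0 and a median of -0.01 (random range -0.10 to 0.16). Slc11a2 (the importer DMT1), Slc40a1 (the exporter ferroportin) and Heph (hephaestin) were under 2-fold, with differences of -0.02, -0.17 and 0.44. Cybrd1, the duodenal iron reductase gene, was below the filter on both arrays. Within the list, Steap4 (4.56-fold), Slc46a1 (3.07-fold) and Lcn2 (2.86-fold) were lower and the metal transporter gene Slc39a8 was 2.02-fold higher. On these arrays the neutrophil list (-1.57) and the Hox genes of groups 10 to 13 (-1.49) were lower as well.

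The acute phase and antimicrobial list went both ways. Slpi read 12.57 in F/F and 10.57 in ΔIE. Saa3, Chil1, Lcn2 and Wfdc2 were 3.04-fold, 2.96-fold, 2.86-fold and 2.79-fold lower, and the list median was -0.66 with 9 of 27 genes at least 2-fold lower. Ang4 and Reg3g were 3.11-fold and 3.05-fold higher, Reg1 read 4.81 in F/F and 6.15 in ΔIE, and Reg3b and Retnlb were 1.70-fold and 1.89-fold higher; without probe sets that can match several transcripts, Reg3b differed by 0.32 in place of 0.76. Ang4 and Retnlb are also goblet cell products, and the lower members S100a8, S100a9, Lyz2 and Nos2 also stand in the neutrophil, macrophage or cytokine lists. The neutrophil (-1.57) and macrophage (-1.07) lists and the posterior Hox genes (-1.49) were lower on the same arrays. The interferon list as a whole lay within its random range, with a median of 0.11. Its largest members went both ways: Ifit1 was 2.56-fold higher and Oas3 1.98-fold, while Cxcl10 and Gbp2 were 3.03-fold and 2.10-fold lower.

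Several lists of epithelial cell types and metabolism were higher on the ΔIE array, while the squamous (-1.17) and acute phase (-0.66) lists were lower. The goblet cell list had a median of 0.55 with 23 of 26 genes above 0; B3gnt6, Ang4 and Spdef, a goblet cell transcription factor, were 3.22-fold, 3.11-fold and 2.69-fold higher, Atoh1 was 1.98-fold higher, and the abundant mucus genes Tff3 and Fcgbp differed by 0.05 and -0.01, while Spink1 was 3.33-fold lower. The enteroendocrine list had a median of 0.86, with 8 genes at least 2-fold higher, including Iapp, Tph1 (3.24-fold), Pcsk1 (6.03 in F/F and 7.57 in ΔIE), Nts (2.70-fold), Chga (2.67-fold), Gcg (2.62-fold) and Sst (2.14-fold). Insl5 and Isl1 went the other way, 6.63-fold and 2.91-fold lower. Colonocyte genes had a median of 0.27; the sodium-proton exchanger gene Slc9a3 was 2.78-fold higher and the bile acid transporter subunit gene Slc51b 2.11-fold, Scnn1g, a subunit of the epithelial sodium channel, read 7.08 in F/F and 5.95 in ΔIE, and Car4 and Aqp8 both differed by -0.05. Genes of fatty acid oxidation and PPAR signalling had a median of 0.55 with 26 of 29 above 0, including Cyp4b1 (2.26-fold), Ppara (2.25-fold) and Pparg (1.92-fold). The adipose list, which shares Cd36 with it, was higher on the same arrays (0.71), as were the skeletal muscle genes Mylpf and Tnnc2. NRF2 and xenobiotic metabolism genes had a median of 0.37, with Ugt2b5 2.92-fold, Cyp2c65 2.46-fold and Aldh1a1 2.06-fold higher and the cystine transporter gene Slc7a11 at 7.44 in F/F and 5.84 in ΔIE. The stem cell and Wnt target list had a median of 0.22, but its mean, 0.04, and its median with probe sets averaged, 0.08, lay within the random range. Kcnq1 was 2.01-fold higher and Lgr5 read 5.84 in F/F and 6.67 in ΔIE, whereas Clu was 3.67-fold lower and Olfm4 read 7.59 and 6.06. These differences stood on the same arrays as the differences in Hox genes, where groups 10 to 13 had a median of -1.49.

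Several groups did not stand apart from random lists. The 45 cell cycle genes had a median of -0.01 and none reached 2-fold. The unfolded protein response (0.07), tight junction and adhesion (0.06), tuft cell (-0.26), exocrine pancreas (0.13) and sex chromosome (0.31) lists lay within their ranges. The cholesterol synthesis list did too, with a median of -0.002 and a mean of 0.05, which differ in sign. With a filter at the 75th percentile the tuft cell median was -1.19, and with a filter on both arrays -0.79, each below its range. With probe sets averaged, and against random lists not matched on expression, it was -0.26, below its range too. At the 75th percentile the tuft list held only Spib (-1.39), Alox5ap (-1.29), Fyb (-1.10) and Cd24a (0.46). In the main setting 4 of its 9 members were above 0 and 5 below. The neutrophil (-1.57) and B cell (-1.49) lists were lower on the same arrays, so these medians are not read as lower tuft cell transcripts. Within the tight junction list the pore-forming claudin genes Cldn2 and Cldn15 were 2.68-fold and 2.24-fold higher and Cldn8 was 2.16-fold lower, and Cldn1 read 6.98 in F/F and 5.24 in ΔIE. Unlike the lists above, the immediate early and heat shock list did stand apart. Its median of -0.19 lay below the random range of -0.07 to 0.13, with no gene at 2-fold. The circadian clock list lay above its range of -0.16 to 0.17, with a median of 0.19 and Dbp 1.34-fold higher. The mean over the clock members, 0.09, lay within the random range. Y-linked Eif2s3y read 8.85 in F/F and 9.02 in ΔIE, so Y-linked RNA was detected on both arrays.

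**Figure D3:**
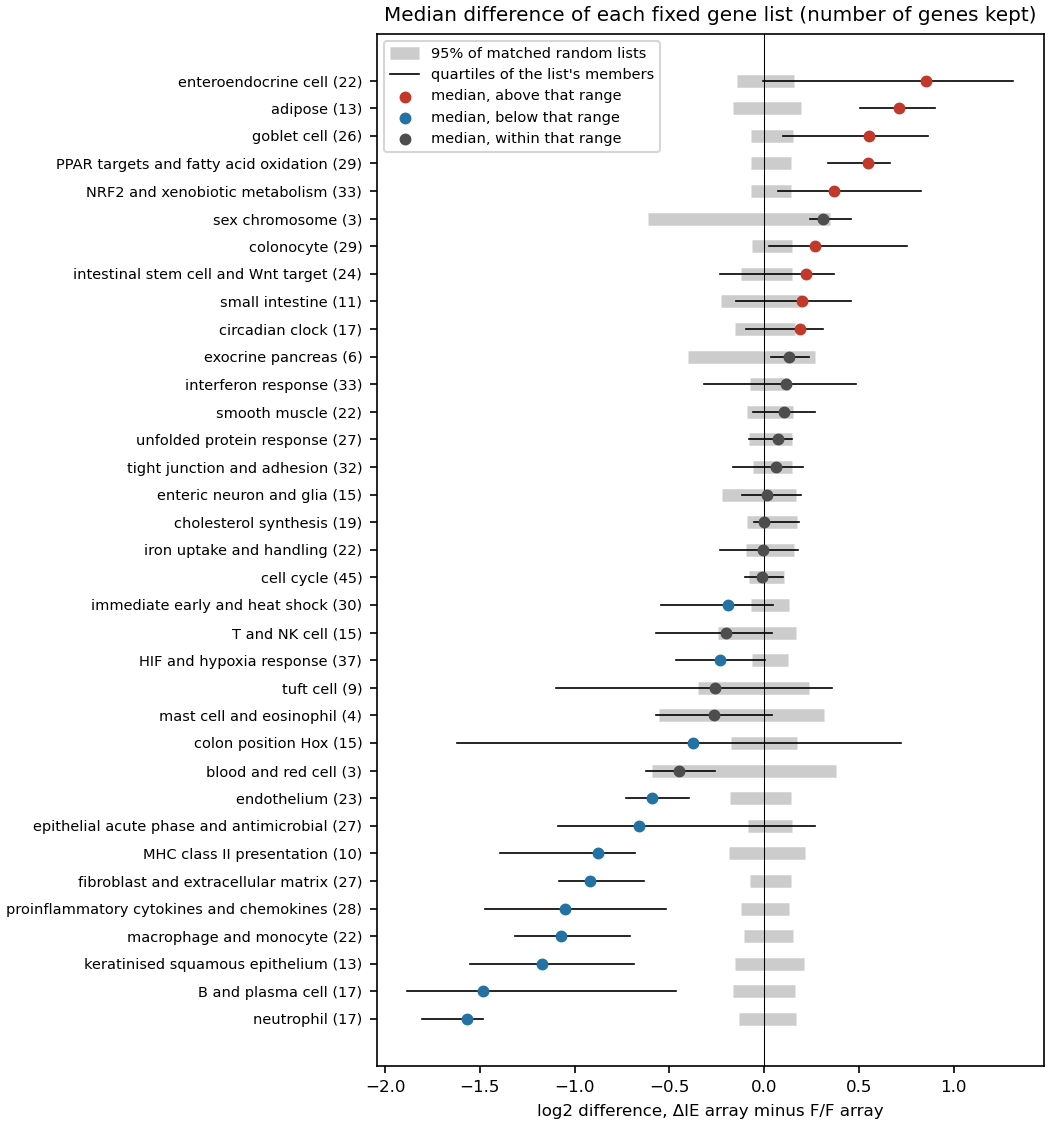
Points are the median log2 difference (x axis, ΔIE minus F/F) of each of the 35 fixed gene lists (y axis, number of genes kept in brackets), thin lines the quartiles of the list's members, and grey bars the middle 95% of 10000 random lists of matched expression. The neutrophil list lies lowest at -1.57 and the enteroendocrine list highest at 0.86; there is 1 array per genotype, so the bars do not measure variation between mice.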

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

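The control probe sets lie outside the gene comparison, and 4 of them differed by more than 2-fold between the arrays. All 4 are for Cre recombinase: AFFX-CreX-3_at was higher on the ΔIE array by 5.07 on the log2 scale, AFFX-CreX-5_at by 4.94, AFFX-r2-P1-cre-3_at by 6.50 and AFFX-r2-P1-cre-5_at by 6.19. The other 41 bacterial control probe sets differed by at most 0.43, with medians of 3.11 in F/F and 3.14 in ΔIE. They include the bioB, bioC and bioD transcripts, which are commonly added to hybridisations together with cre. Among these AFFX-BioDn-3_at was the highest, at 7.26 in F/F and 7.49 in ΔIE, while AFFX-BioDn-5_at read 2.96 and 2.87. No comparable rise in these controls went with the Cre signal. Probe sets for 18S ribosomal RNA were higher on the ΔIE array by 0.37 to 0.69, and those for the 3' and 5' ends of Gapdh differed by -0.08 and -0.08.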

How the results depend on the processing

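The setting without members shared with another list was chosen after seeing the data. With 1 array per genotype no replicate could be left out, and no paired analysis was possible because each genotype has a single array. The pseudocount alternative did not apply to log2 values. The count of genes lower on the ΔIE array was 381 with a filter at the 75th percentile, where fewer genes were tested (7496), against 631. With a threshold of 1.5-fold the counts were 520 higher and 1267 lower, and with 3-fold 20 higher and 177 lower. In all of the alternatives the genes lower outnumbered those higher, and 15 of 20 recomputed counts stayed within 1.5 times. The Epas1 difference of -0.13 ran from -0.19 to 0.02, the last as the mean over its probe sets. The cytokine and chemokine median of -1.05 was -0.72 without a filter, -1.28 with a filter at the 75th percentile and -0.91 without members shared with another list, and stayed below its random range in each. The iron list had a mean of -0.18, still within its range; the cause was not tested. The Hox list turned from -0.38 to 0.37 (75th percentile) and 0.11 (both arrays above the filter), because these filters leave out lower members dim on 1 array or both. Of 21 lists outside their range, 17 stayed on the same side in all alternatives; the exceptions were the Hox, stem cell and Wnt target, circadian clock and small intestine lists. Of lists within their range, the T and NK cell, mast cell and eosinophil, tuft cell and smooth muscle lists lay outside it in at least 1 alternative. Of 5050 recomputed values of 769 genes, 24 moved by over 0.41, the 95% gap between probe sets of 1 gene, and 61 genes changed sign in an alternative, among them Egr3 and Synpo2, but 0 of these were at least 2-fold. Other genes at 2-fold were not recomputed one by one.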

Other observations

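The tests on Hox genes, smooth muscle genes and list medians against random lists were chosen after the differences had been seen; those on further skeletal muscle and interferon genes were written before those genes were looked at.

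Outside the lists described above, Tnfsf11 (the cytokine RANKL) read 7.52 in F/F and 5.41 in ΔIE, and Tnfrsf11b (its decoy receptor osteoprotegerin) 7.35 and 4.83. Both differences were smaller with probe sets averaged: Tnfsf11 differed by -1.63, and Tnfrsf11b by -1.89 in place of -2.53. Genes of fast skeletal muscle were higher, with Myh1 2.85-fold and Myl1 2.72-fold higher; averaged over its probe sets, Myh1 differed by 1.06 in place of 1.51. These genes were chosen after their values were seen.

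The first pattern is the lower level of posterior Hox genes on the ΔIE array. A more distal stretch of colon in the F/F RNA stays open: across the 19 Hox genes kept the Spearman rho of difference on paralog group was -0.69 (Pearson r = -0.73, across genes, which are not independent replicates), but without the 7 genes of groups 10 to 13 that prompted the pattern it was -0.09, so the correlation gives no separate evidence. The squamous list (-1.17) and Insl5 (6.63-fold) were lower too, on the same 2 arrays. Less connective tissue in the ΔIE RNA stays open, because the median of the 8 Hox genes of groups 5 to 9 was 0.11 with 4 above 0 and an SD of 1.09; another form of this test, the median of the 5 Hoxb genes of groups 3 to 9 (1.03), was dropped because those genes were picked with their values in view, and the condition on the SD was added after the values were seen. An effect of genotype was not tested and stays open.

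The second pattern is the lower level of cytokine, neutrophil, macrophage, B cell and matrix genes. A smaller share of all non-epithelial tissue, muscle included, is argued against by the smooth muscle list. Its median was 0.10 (mean over members 0.18) beside -0.92 for the matrix list, values known when the test was chosen. A smaller share of leukocytes and connective tissue without muscle is not addressed by that list and stays open. A shift common to all genes would move matched random lists as much. The matrix list, nearest to its random lists of the 5, differed from their median by -0.95. The 5 lists were chosen because they lay below their ranges, so this outcome was fixed beforehand and is no separate test. It shows only that these genes were lower than genes of like expression. The median of all genes kept, 0.019, was tried first and decides nothing, as quantile normalization sets it near 0. A more distal F/F sample cannot be told apart from an effect of genotype for these genes, since the Hox genes of groups 10 to 13 (median -1.49) differed on the same 2 arrays. Fewer infiltrating leukocytes through the genotype stays open as a biological explanation and was not tested.

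The third pattern is the skeletal muscle genes, higher on the ΔIE array. If skeletal muscle RNA were present there, other muscle genes would be higher too. Of 25 further muscle genes 9 were above the filter, 8 of these were higher, and their median was 0.54, above the random range of -0.50 to 0.25; Acta1 was 2.43-fold higher, and Eno3, which other tissues express as well, 3.52-fold lower. A small amount of skeletal muscle in the dissected tissue may account for this, and no biological explanation was tested.

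A hypothesis concerned the interferon list, in which type I genes such as Ifit1, Oas3 and Irf7 were higher and genes responsive to interferon gamma such as Cxcl9 (1.90-fold) and Gbp2 lower. In genes not looked at before, the median of 14 further type I genes was 0.07 and that of 12 further interferon gamma genes -0.39, a gap of 0.47. The gap met the size and direction set beforehand, but only the interferon gamma median lay outside its random range (-0.15 to 0.20). The type I median lay inside its range, with 7 of 14 genes above 0, so these values do not show higher type I responses. The macrophage (-1.07), class II (-0.88) and neutrophil (-1.57) lists and the posterior Hox genes (-1.49) were lower on the same arrays, so the interferon gamma median is not read as a lower response per cell.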
